A study of Homo sapiens with 4 samples.

How the data were processed

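Libraries were made from ES2 ovarian cancer cells, 2 from RNA precipitated with an antibody against RBMS1 and 2 from input RNA, and were sequenced on an Illumina platform, per the labels' protocols. The series' design text names a normal IgG control, while the labels of the libraries give Input; no IgG library was analysed here, so recovery is measured against the lysate and not against nonspecific precipitation. The authors deposited raw counts per gene, whole numbers with no normalization, in a table of 60623 Ensembl gene identifiers. Each column was matched to its library by the name in the labels. The submitters' processing notes name hg38, MACS2 and DESeq2, without a version or a role. The read counter, the aligner, the annotation and whether the counting used strand are not given in the sources used here. No peak list was analysed here.

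Symbols were found for 60295 identifiers in a gene name table, 58516 identifiers were in GENCODE release 29, and 19 had a symbol in neither. Gene positions, types, exon overlaps, and transcript and 3' UTR sequences came from GENCODE release 29 on GRCh38 (hg38). Of the genes, 25123 had at least 1 count. Total counts were 28134117 (RIP 1), 22723505 (RIP 2), 26434737 (Input 1) and 30969377 (Input 2), and 20519, 19589, 20420 and 20890 genes had a count. The 10 most abundant genes took 6.53%, 21.7%, 9.44% and 10.1% of the counts. A chi-square per degree of freedom of 728 for the RIP pair and 236 for the Input pair shows that neither pair is a duplicate of a single library; it does not show separate cultures.

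RIP was compared with Input in edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test (glmQLFit and glmQLFTest) with TMM normalization. The TMM factors were 1.02 for RIP 1, 1.05 for RIP 2, 0.886 for Input 1 and 1.05 for Input 2. Genes were kept by filterByExpr with a minimum count of 10, which left 14157, of which 12045 are protein-coding. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Fitted log2 fold changes used a prior count of 0.125 and levels are CPM on TMM-scaled library sizes, given as mean ± SD of 2 libraries. Log2 CPM values for correlations used a prior count of 2. Standard errors were taken from the F statistic with a median of 14.3 degrees of freedom. The common dispersion was 0.192, a biological coefficient of variation of 43.9%. The tests were tested on simulated counts drawn with the means, library sizes and dispersions of the 14157 genes, with 200 genes changed in each of 5 runs. The test recovered 0.8% of 250 genes changed 2-fold, 14.4% of 250 changed 4-fold, 63.2% of 250 changed 8-fold and 93.6% of 250 changed 16-fold, with 17 false calls among 69785 unchanged genes. Simulated genes were independent, and each had the same dispersion in RIP and Input. The real RIP pair differed more than the Input pair, so these rates need not hold for the real libraries.

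The gene lists, the rule for named genes, the tests of RIP against Input for genes and lists, and all but 2 of the alternatives were fixed before the data were examined; some tests of explanations were chosen later, as stated beside them. The rule named RBMS1 and NEDD4, up to 12 genes in each direction with the largest fold change among those called, with a mean of at least 5 CPM and the same sign in both replicate numbers, and from each tested list up to 2 members in each direction with the smallest p; pseudogenes and genes without a symbol were left out of the second part. It gave 6 genes lower and 0 higher in the second part. Some of the list members it named are left out of the text. There were 25 lists, of which 20 had at least 5 tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over those 20; of the other 5, 4 are described gene by gene and 1 is not reported here. The lists of single genes covered the study genes, the RBMS family, reported RBMS1 targets, NEDD4-type ligases, PI3K-AKT-mTOR, Hippo and TGF-beta genes, mesenchymal and epithelial genes, AU-rich mRNAs, cell cycle, ferroptosis, RNA-binding and ubiquitin ligase genes, noncoding RNAs, and markers of endothelial, adipocyte and liver cells. Ribosomal protein, mitochondrially encoded, histone, oxidative phosphorylation, ZNF, collagen, proteasome and solute carrier genes were taken by the pattern of their symbols, which also takes in pseudogenes that share the pattern.

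Shares of counts have Wilson intervals at 95%, and a count of 0 was read as allowing up to 3 counts. The alternatives were a replicate block, DESeq2's size factors, library-size scaling, no filter (at least 1 count), a filter of at least 50 counts in 2 libraries of a group, each library left out in turn, the Wald test of DESeq2 1.42.0, glmTreat against a 1.5-fold change, a 2-fold minimum, an adjusted p under 0.01, camera with an estimated correlation, and fry; leaving out the mitochondrially encoded genes and an adjusted p under 0.1 were added after the data were seen. DESeq2 gave no adjusted p for 275 genes, which stayed uncalled. When a library was left out, the lone library of its group was assumed to vary like the other group. Sequence features were tested on the 11577 protein-coding genes with a 3' UTR of at least 50 nucleotides, with linear models in Python 3.11.15 (NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3). Figures were drawn with matplotlib 3.10.9.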

Results

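RNA bound by RBMS1, an RNA-binding protein of the single-stranded nucleic acid interacting family, was measured by RNA immunoprecipitation and sequencing (RIP-seq) in ES2, an established human ovarian cancer cell line. In this assay an antibody against the protein pulls it down with the RNA attached to it, and that RNA is sequenced beside the RNA of the starting lysate. There were 4 libraries, 2 from the anti-RBMS1 precipitate (RIP) and 2 from the lysate (Input). The total counts were 28134117 in RIP 1, 22723505 in RIP 2, 26434737 in Input 1 and 30969377 in Input 2. A count of 1 was worth between 0.0308 CPM (counts scaled to the TMM-adjusted library size) in Input 2 and 0.0427 CPM in Input 1. A count of 0 allowed a level of up to 0.0925 CPM in Input 2 and up to 0.128 CPM in Input 1. These limits and the intervals on shares below cover counting error only. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Positions of genes are those of GENCODE release 29 on GRCh38 (hg38).

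The RIP libraries differed from each other more than the Inputs did, with mitochondrial and ribosomal protein RNA among what differed. RNAs encoded in the mitochondrial genome took 1.57% of the counts in RIP 1 (95% Wilson interval 1.57 to 1.58) and 19.98% in RIP 2 (19.96 to 19.99). Their share was 4.35% in Input 1 (4.34 to 4.36) and 7.30% in Input 2 (7.29 to 7.31). mRNAs of the cytosolic ribosomal proteins took 16.2% in RIP 1, 7.20% in RIP 2, 17.6% in Input 1 and 10.7% in Input 2. Across the 14157 genes tested, the Pearson correlation of log2 CPM was 0.965 between the Inputs and 0.913 between the RIP libraries. RIP 1 correlated more closely with Input 1 (0.942) and Input 2 (0.943) than with RIP 2. The log2 ratio of RIP to Input correlated between the replicate numbers across genes at 0.616 (Pearson) and 0.605 (Spearman); genes are not independent replicates.

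The comparison of RIP with Input asks which RNAs were recovered with RBMS1 beyond their abundance in the lysate, and the series names NEDD4, which encodes a HECT-type ubiquitin ligase, as the mRNA of interest. NEDD4 (ENSG00000069869, chromosome 15, 55826922 to 55993746, minus strand) stood at 22.6 ± 18.2 CPM in RIP (SD, n = 2) and 7.44 ± 4.73 CPM in Input (SD, n = 2). Its counts were 280 in RIP 1, 846 in RIP 2, 96 in Input 1 and 350 in Input 2, so that RIP 1 at 9.72 CPM lay below Input 2 at 10.8 CPM. The log2 fold change of NEDD4, RIP over Input, was 1.60 (SE 0.70, 95% interval 0.10 to 3.10), and edgeR's quasi-likelihood test gave an adjusted p of 0.268 (Benjamini-Hochberg). RBMS1 itself (ENSG00000153250, chromosome 2, 160272151 to 160493794, minus strand) stood at 68.5 ± 36.4 CPM in RIP (SD, n = 2) and 30.4 ± 9.79 CPM in Input (SD, n = 2). Both RIP libraries lay above both Inputs for RBMS1, with a log2 fold change of 1.17 (SE 0.59, 95% interval -0.10 to 2.44) and an adjusted p of 0.329 by edgeR's quasi-likelihood test. Neither difference therefore passed the threshold against the spread between replicates. Without RIP 1 the log2 fold changes were 2.25 for NEDD4 and 1.63 for RBMS1, with the lone RIP library giving no spread of its own. A block by replicate number put NEDD4 past the threshold, as given with its limits below. The log2 fold change without RIP 2 was 0.34 for NEDD4 and 0.45 for RBMS1. Whether either gene passed the threshold thus depended on the setting, and a fit with a lone library in a group decides little.

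The paralogs RBMS3 and RBMS2 had log2 fold changes of 1.03 and 0.22, and none of the 3 RBMS genes passed the test. Of 4 mRNAs reported elsewhere as RBMS1 targets, none passed it either. SLC7A11, the cystine transporter subunit, had a log2 fold change of 1.40 (SE 0.56), with both RIP libraries above both Inputs. SDCBP, which encodes syntenin, had 1.04, the scaffold gene AKAP12 had 0.25 and the galactosyltransferase gene B4GALT1 had -0.24. Without RIP 1 SLC7A11 stood at 1.59, and a block by replicate number put it past the threshold, as given with its limits below. Without RIP 2 the values were 0.30 for RBMS3, 0.61 for SDCBP, 1.15 for SLC7A11, -0.29 for RBMS2 and -1.26 for AKAP12. RBMS3 stood at 0.51 without Input 1, RBMS2 at -0.03 without Input 2, and AKAP12 at -0.26 without Input 1.

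**Figure D1:**
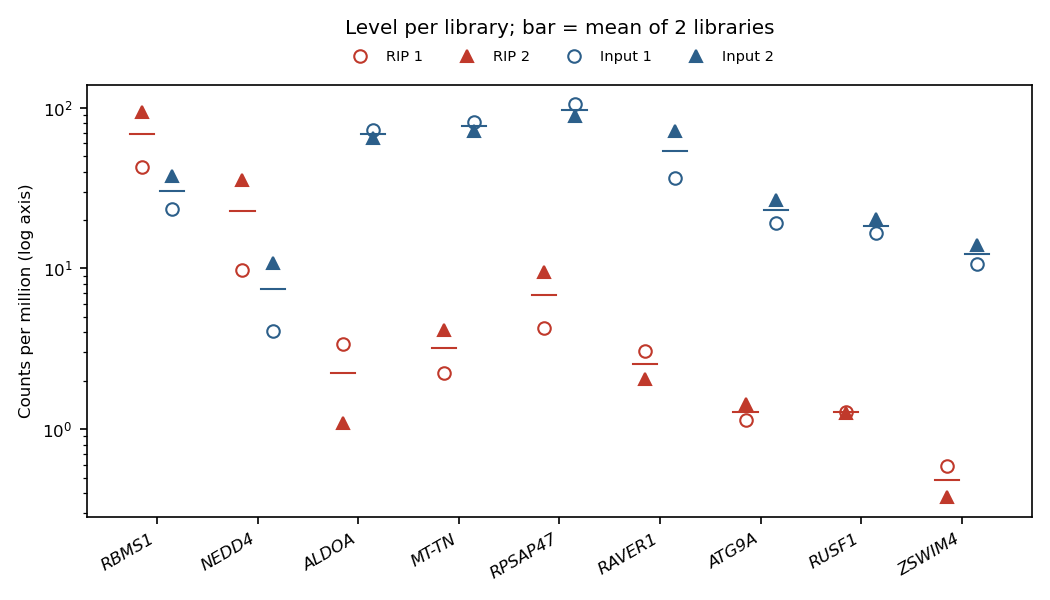
Level of 9 genes in each library, in CPM on a log axis; circles are replicate 1, triangles replicate 2, red RIP and blue Input, and each bar is the mean of 2 libraries. NEDD4 in RIP 1 (9.72 CPM) lies below Input 2 (10.8 CPM), while ALDOA is at 2.23 CPM in RIP against 68.6 CPM in Input on average.

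Over all genes, 12 RNAs fell in RIP and 0 rose, among them the mRNA of the glycolytic enzyme aldolase A. ALDOA (ENSG00000149925, chromosome 16, 30064164 to 30070457, plus strand) was 30.6-fold lower, at 2.23 ± 1.61 CPM in RIP and 68.6 ± 5.61 CPM in Input (SD, n = 2 each). ZSWIM4 (ENSG00000132003, chromosome 19, 13795460 to 13832230, plus strand) was 25.2-fold lower, at 0.484 ± 0.151 against 12.4 ± 2.39 CPM. The mitochondrial asparagine tRNA MT-TN (ENSG00000210135, chromosome M, 5657 to 5729, minus strand) was 24.1-fold lower, at 3.19 ± 1.36 against 76.7 ± 6.64 CPM. The splicing co-repressor gene RAVER1 (ENSG00000161847, chromosome 19, 10316212 to 10333640, minus strand) was 21.0-fold lower, at 2.55 ± 0.709 against 53.9 ± 24.5 CPM. ATG9A (ENSG00000198925, chromosome 2, 219219380 to 219229717, minus strand), which encodes the membrane protein of autophagosome formation, was 17.8-fold lower, at 1.29 ± 0.197 against 22.9 ± 5.47 CPM. RUSF1 (ENSG00000140688, chromosome 16, 31489471 to 31509309, minus strand) was 14.5-fold lower, at 1.27 ± 0.0196 against 18.4 ± 2.44 CPM. The log2 fold changes of these 6 genes ran from -4.93 (ALDOA, SE 0.71) to -3.85 (RUSF1, SE 0.62). Their adjusted p by edgeR's quasi-likelihood test (Benjamini-Hochberg) lay between 0.0214 and 0.0311, and both RIP libraries were below both Inputs for each. Library-size scaling alone ended all 12 calls (adjusted p of 0.102 for ALDOA by edgeR's quasi-likelihood test, with a log2 fold change of -4.84). Without Input 2 the adjusted p was 0.0505 for RAVER1, 0.0555 for ATG9A and 0.0736 for RUSF1 by the same quasi-likelihood test.

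The other 6 RNAs that fell stood outside the rule for named genes and were picked out after their values were seen. SLC39A1, a zinc importer gene, had counts of 2 and 0 in RIP against 62 and 71 in Input. SRXN1, the sulfiredoxin gene, had 2 and 1 against 59 and 133, and ABHD16A had 0 and 1 against 48 and 67. The antisense RNA ABALON had 5 and 2 against 136 and 162, and the antisense gene ENSG00000248607 had 2 and 5 against 72 and 251. RPSAP47, a processed pseudogene of the ribosomal protein gene RPSA, had 123 and 225 against 2460 and 2882, and reads shared with its parent gene make that value uncertain. Of the 12 genes, 9 overlapped an exon of another gene on either strand; for ALDOA these were AC093512.1 and AC093512.2, for RUSF1 AC026471.2 and SLC5A2, and for ABALON BCL2L1. The strand setting of the counting is not given in the sources used here, so reads of such overlapping genes cannot be assigned with certainty.

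At an unadjusted p under 0.05, edgeR's quasi-likelihood test gave 1488 genes higher and 925 lower in RIP, 17.0% of those tested, where chance gives 708 genes in all. The smallest adjusted p of a gene higher in RIP was 0.0529, shared by CPNE8, a copine gene picked out after its values were seen, with a log2 fold change of 4.14 (SE 0.77). Both RIP libraries lay above both Inputs for 3790 genes (26.8%) and below both for 3357 (23.7%). Chance gives 16.7% each only if every order of the libraries is equally likely. Trends shared by many genes break this, as with transcript GC content for RIP 2 over RIP 1 (Spearman's rho -0.57) and Input 2 over Input 1 (-0.25). The excess therefore does not by itself show recovery with RBMS1. DESeq2's Wald test called 364 genes higher and 319 lower on the same counts, and edgeR with DESeq2's size factors called 5 and 33. The count changed with the library left out, with more genes called without a RIP library than without an Input library. The group that loses a library has no spread of its own, so these counts rest on the other group's spread.

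**Figure D2:**
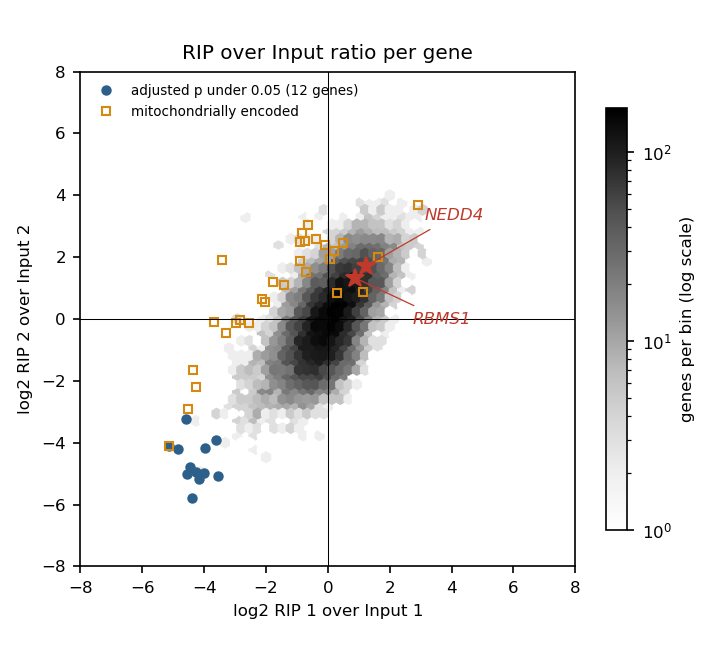
Log2 ratio of RIP 1 to Input 1 (horizontal) against RIP 2 to Input 2 (vertical) for the 14157 genes tested; grey shading is the number of genes per bin on a log scale, blue points are the 12 genes past the threshold, orange squares are mitochondrially encoded RNAs and red stars are RBMS1 and NEDD4. The ratios correlate at 0.616 across genes, and all 12 genes past the threshold lie at negative ratios on both axes.

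Among the gene lists, mRNAs of zinc finger (ZNF) and histone genes rose in RIP relative to other genes, and those of ribosomal proteins and solute carriers fell, by camera with its preset correlation between genes. With an estimated correlation 0 of the 20 lists tested passed (camera adjusted p = 0.896 for each of these 4). Camera then tests on the residual degrees of freedom of 4 libraries, too few to make a pass likely for any list. For solute carriers the estimate (0.00495) lay below the preset 0.01, yet camera's unadjusted p rose from 0.00375 to 0.0717. The estimate was 0.223 for ZNF, 0.482 for histone and 0.865 for ribosomal protein genes, against the preset 0.01. Such correlations by themselves weaken the evidence, so the preset camera p-values of these lists may be too small. The estimates rest on the same few residual degrees of freedom. The histone and ribosomal protein medians changed sign without RIP 2. Camera results with a library left out, here and below, use the preset correlation and rest on the lone library left in that group. The 376 ZNF genes, mostly zinc finger transcription factors, had a median log2 fold change of 0.67, with 272 positive and both RIP libraries above both Inputs for 162 (camera adjusted p = 0.000134). ZNF121 had 2.65 (SE 0.60) and ZNF624 had 3.60, while ZNF384 had -2.41 and ZNF598, a sensor of collided ribosomes, had -1.98; none of the 376 passed the test alone. Without RIP 2 the ZNF median was 0.23 (camera adjusted p = 0.0318), with ZNF121 at 2.26 and ZNF624 at 1.81. The 55 histone genes had a median of 1.15, with 51 positive (camera adjusted p = 0.00273), but the replicates differed in sign. Their median was -1.07 for RIP 1 over Input 1 and 2.64 for RIP 2 over Input 2, the library with 19.98% mitochondrial counts. H1-4, a linker histone gene, had counts of 22 in RIP 1, 1065 in RIP 2, 35 in Input 1 and 41 in Input 2, and H2AC20 had a log2 fold change of 2.86, and of 0.09 without RIP 2. Without RIP 2 the histone median was -0.96, with a camera adjusted p of 0.000446, and without Input 2 it was 0.85, with 0.13.

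The 84 ribosomal protein genes had a median log2 fold change of -0.33, with 54 negative (camera adjusted p = 0.00273), and none passed the test alone. RPL17 had -3.12 (SE 0.75) and RPL39L had -2.57, while RPS7 had 1.04, and 0.43 without RIP 1. Their median was 0.13 without RIP 2 and 0.18 without Input 1, with camera adjusted p of 0.885 and 0.784. The 186 solute carrier genes had a median of -0.31, with 119 negative and both RIP libraries below both Inputs for 70 (camera adjusted p = 0.0187). SLC39A1 was the member that fell, and adjusted over the list alone 2 members were lower. SLC4A2, an anion exchanger gene, had -2.87 (SE 0.62), and SLC35A1, the CMP-sialic acid transporter gene, had 2.34.

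**Figure D3:**
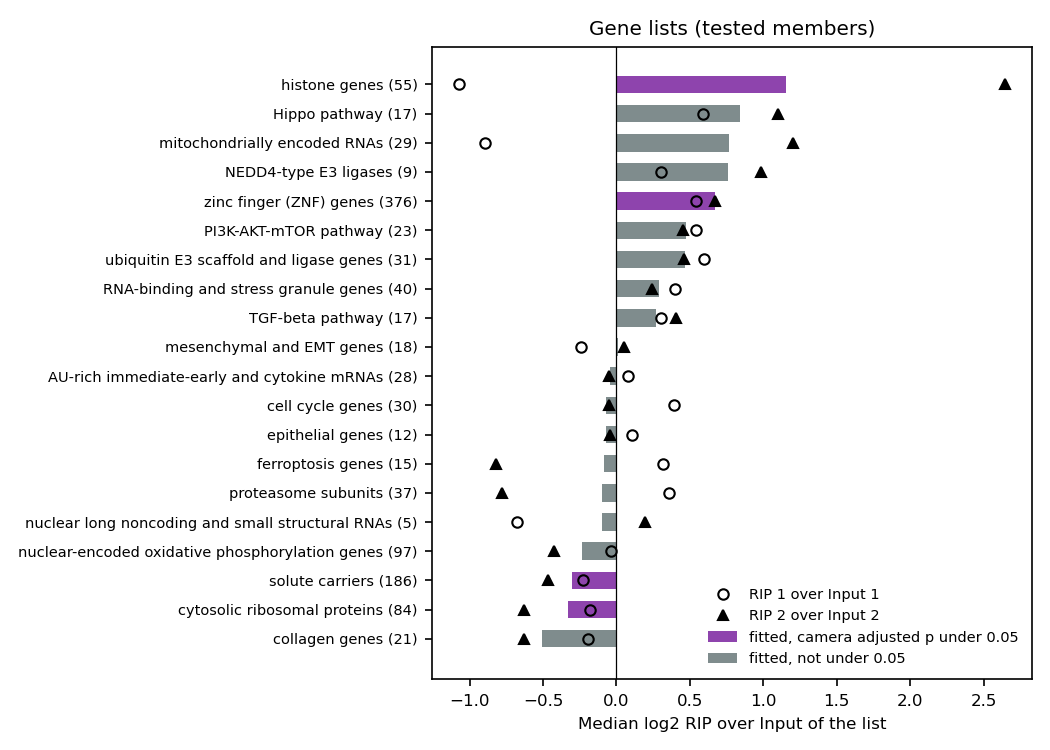
Median log2 ratio of RIP to Input of each of the 20 lists tested, with the number of tested members in brackets; bars are fitted values, purple where camera's adjusted p was under 0.05, circles are RIP 1 over Input 1 and triangles RIP 2 over Input 2. The histone genes range from -1.07 to 2.64 between the replicates and the ZNF genes from 0.54 to 0.67.

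The pathway lists closest to NEDD4 had positive medians without passing camera's test. Of 9 NEDD4-type ubiquitin ligase genes 8 were positive, with a median log2 fold change of 0.76 (camera adjusted p = 0.203), and WWP2 had 1.55. Of 17 Hippo pathway genes 13 were positive, with a median of 0.84 (camera adjusted p = 0.0831) and 1 higher adjusted over the list alone; MOB1B, a LATS kinase activator gene, had 2.70 (SE 0.72) and LATS1 had 2.13. Of 23 PI3K-AKT-mTOR genes 15 were positive, with a median of 0.47 (camera adjusted p = 0.225). RICTOR, the mTORC2 scaffold gene, had 2.47 and FOXO1 had 2.19, while AKT1 had -1.55 and MLST8 had -1.62. Of 17 TGF-beta pathway genes 12 were positive, with a median of 0.27 (camera adjusted p = 0.203) and 2 higher adjusted over the list alone; SKIL had 2.18 and the receptor gene TGFBR1 had 1.84. Of 31 ubiquitin E3 scaffold and ligase genes 24 were positive, with a median of 0.47 (camera adjusted p = 0.144). Adjusted over that list alone 3 were higher and 2 lower; SIAH1 had 3.29 (SE 0.69) and XIAP had 2.79, while VHL had -2.16 and STUB1 had -2.14. Of 40 RNA-binding and stress granule genes 28 were positive, with a median of 0.29 (camera adjusted p = 0.231), and MBNL1 had 2.45, QKI had 2.37 and YBX1 had -1.60. Without RIP 1 all of these lists but PI3K-AKT-mTOR passed, with camera adjusted p from 0.0158 (Hippo, median 1.12) to 0.0366 (TGF-beta, 0.49), and without Input 2 the Hippo (0.0255), ubiquitin ligase (0.0255) and RNA-binding (0.0122) lists did; the Hippo list also passed with no filter (0.0359). None of them passed without RIP 2 or without Input 1. Without RIP 2 the medians were 0.05 (NEDD4-type, camera direction lower), 0.46 (Hippo), 0.37 (PI3K-AKT-mTOR), 0.0097 (TGF-beta), 0.16 (ubiquitin ligase) and -0.0046 (RNA-binding), and without Input 1 the TGF-beta and RNA-binding medians were -0.02 and -0.12. The higher values of single genes were smaller without RIP 2, at 0.05 for WWP2, 0.55 for FOXO1, 0.62 for QKI, 0.85 for LATS1, 1.03 for SKIL, 1.15 for RICTOR, 1.23 for XIAP, 1.55 for MBNL1, 1.56 for TGFBR1, 1.80 for MOB1B and 2.07 for SIAH1.

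Lists of cell state held members on both sides of 0, and no gene of these passed the test over all genes. The 30 cell cycle genes had a median log2 fold change of -0.07 (camera adjusted p = 0.754), with 2 lower adjusted over the list alone. RB1 had 2.03 and CDK1 had 1.80, while CDK4 had -2.97 and the replication helicase gene MCM2 had -2.90. The 15 ferroptosis genes had a median of -0.08 (camera adjusted p = 0.144), and adjusted over the list alone 1 was higher and 3 were lower. ACSL4, which loads polyunsaturated fatty acids onto coenzyme A, had 2.38 (SE 0.69), LPCAT3 had -3.70 (SE 0.64) and the ferritin heavy chain gene FTH1 had -3.96 (SE 0.97). The 18 mesenchymal genes had a median of 0.01 (camera adjusted p = 0.754), with AXL at -1.32, and the 12 epithelial genes had a median of -0.07 but a mean of 0.16 (0.879). The 28 AU-rich immediate-early and cytokine mRNAs had a median of -0.04 and a mean of 0.03 (camera adjusted p = 0.830), with ZFP36 at 1.46 and its paralog ZFP36L2 at -1.20. The 97 oxidative phosphorylation genes encoded in the nucleus had a median of -0.24 (camera adjusted p = 0.225) and the 21 collagen genes had -0.51 (0.225). The 37 proteasome subunit genes had a median of -0.10 (camera adjusted p = 0.209), with 2 lower adjusted over the list alone, PSMA2 at 1.79 and PSMA6 at -2.69. Without RIP 2 the values were 1.13 for RB1, 1.14 for ACSL4, 0.79 for ZFP36 and -2.09 for ZFP36L2, and without Input 2 MCM2 stood at -1.55. The oxidative phosphorylation list was called in opposite directions without RIP 1 (median -1.04, camera adjusted p = 0.000123) and without RIP 2 (0.21, 0.0409), and was lower without Input 2 (-0.51, 0.000448). Lower calls also came for the proteasome list without RIP 1 (-0.97, 0.0042), the mesenchymal list without RIP 2 (-0.62, 0.0434), and the collagen list without RIP 2 (-0.79, 0.0409) and without Input 1 (-0.81, 0.0209).

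The 29 mitochondrially encoded RNAs had a median log2 fold change of 0.77 but a camera direction of lower (adjusted p = 0.621), and the replicates differed in sign, with -0.90 for RIP 1 over Input 1 and 1.20 for RIP 2 over Input 2. The list's median was 1.67 without RIP 1 and -1.79 without RIP 2. On all 4 libraries the correlation estimated within the list was 0.924. Camera's adjusted p with it was 0.896, on too few residual degrees of freedom to make a pass likely. MT-TN fell, and adjusted over the list alone 1 member was higher and 3 were lower; the tRNA MT-TR had 3.63 (SE 0.97), and 1.39 without RIP 2, and MT-TY had -3.83 (SE 0.73). Of 20 nuclear noncoding and small structural RNAs 5 could be tested (median -0.10, camera adjusted p = 0.466), with 1 lower adjusted over the list alone; without RIP 2 the list was lower (-0.87, 0.0165). RN7SL1, the signal recognition particle RNA, had counts of 73 and 419 in RIP against 35932 and 2827 in Input. MALAT1 had a log2 fold change of 2.59, and -1.34 without RIP 2. Of 11 endothelial, adipocyte and liver markers only CDH5 reached the filter, with a log2 fold change of -0.44, and leaving out Input 2 gave 0.21.

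The RIP to Input ratio varied with base composition. In 5 equal groups of the 11577 protein-coding genes with an annotated 3' UTR, from the lowest to the highest transcript GC content, the median log2 fold change was 0.92, 0.44, -0.03, -0.40 and -0.48. Spearman's rho with transcript GC across genes was -0.36 for RIP 1 over Input 1 and -0.61 for RIP 2 over Input 2, and within the groups it was -0.57 for RIP 2 over RIP 1 and -0.25 for Input 2 over Input 1. NEDD4, with a transcript GC of 37.7%, ranked at percentile 93.8 of these genes and at percentile 81.2 of the 500 nearest to it in GC. RBMS1, with 41.4%, ranked at percentile 86.6 and at 75.6 of its 500 nearest. The ZNF genes had a median transcript GC of 44.5%, against 49.9% in the other genes.

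**Figure D4:**
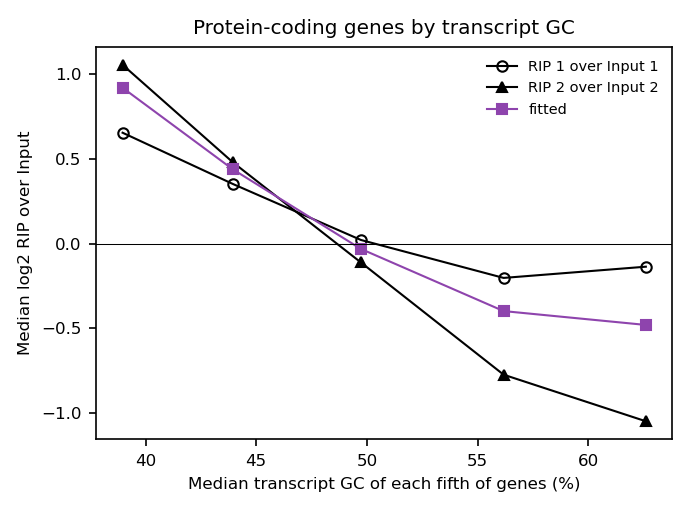
Median log2 ratio of RIP to Input (vertical) against the median transcript GC in percent (horizontal) of 5 equal groups of 11577 protein-coding genes; circles are RIP 1 over Input 1, triangles RIP 2 over Input 2 and squares the fitted value. The fitted median goes from 0.92 in the group lowest in GC to -0.48 in the highest, and the slope is steeper for RIP 2.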

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

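The settings without the mitochondrially encoded genes and with an adjusted p under 0.1 were tests chosen only after the result was seen. Genes higher and lower in RIP, 0 and 12 as reported, numbered 5 and 33 with DESeq2's size factors, 342 and 302 with no filter (25123 genes tested), 75 and 103 with the strict filter (11454 tested), 24 and 59 without the mitochondrially encoded genes, 364 and 319 by DESeq2's Wald test, and 97 and 142 at an adjusted p under 0.1. Library-size scaling alone and an adjusted p under 0.01 left 0 and 0; glmTreat against 1.5-fold left 0 and 11. With each library left out in turn the count ran from 0 (without Input 1 or Input 2) to 1899 (without RIP 1) higher and from 12 to 1460 lower; the cause was not tested. The 12 genes were kept by DESeq2's size factors, no filter, DESeq2's Wald test and without RIP 1 or RIP 2; 11 were kept without Input 1 and 8 without Input 2, and 11 of the 11 tested were kept by the strict filter. Of the 20 gene lists tested 4 passed camera as reported and 0 passed with fry. With an estimated correlation 0 passed. The few residual degrees of freedom made a pass unlikely, and for the ZNF, histone and ribosomal protein lists so did estimates above the preset correlation. The correlation of the replicate ratios, 0.616, was 0.501 with no filter and 0.663 with the strict filter.

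For the genes named and the 4 lists called, reversals came only from leaving out a library; medians near 0 of lists not called also changed sign elsewhere, such as the mesenchymal median (0.01), -0.47 with no filter, and the AU-rich median (-0.04), 0.07 with the strict filter. The ribosomal protein median ran from -1.14 to 0.18 (0.13 without RIP 2, 0.18 without Input 1) and the histone median from -0.96 (without RIP 2) to 2.10. The lowest and highest log2 fold changes were -0.89 and 5.01 for H1-4, -0.29 and 0.57 for RBMS2 (-0.03 without Input 2), -1.26 and 1.00 for AKAP12 (-0.26 without Input 1), -1.34 and 3.54 for MALAT1, and -0.89 and 0.21 for CDH5. NEDD4 ran from 0.34 to 2.46 and RBMS1 from 0.45 to 1.63 with no change of sign.

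A replicate block gave 1417 genes higher and 1067 lower, kept the 12 genes and put NEDD4 past the threshold (log2 fold change 1.49, adjusted p = 0.0105 by edgeR's quasi-likelihood test). By the same quasi-likelihood test SLC7A11 passed with the block (1.42, adjusted p = 0.0219). RBMS1 (0.101), SDCBP (0.152), AKAP12 (0.988) and B4GALT1 (0.780) did not. The deviations of samples with the same number correlated at 0.459, but with 2 pairs and labels that do not say what the numbers share, the numbers do not establish that the samples are paired. Alternatives planned for normalized values or peak lists do not apply to a table of counts and were not run. Depth limits the genes with 0 to 5 counts in RIP, whose fold changes are not given.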

Other observations

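The tests of mitochondrial and histone RNA, the comparison of AUAUA between the RIP libraries, the description by gene type and the residual of the ZNF genes were chosen only after the result was seen. Among gene types, the RNAs annotated as sense intronic had a median log2 ratio of RIP to Input of 1.35 over 75 genes, of which 62 were positive, and with 1.15 and 1.36 in the replicates. The 6 microRNA genes tested had a median of 1.90. Long intergenic RNAs had a median of 0.37 over 518 genes, with 331 positive, but 0.02 for RIP 1 over Input 1. All 9 small nucleolar RNAs tested were negative, with a median of -3.11 and with -2.01 and -2.53 in the replicates. Processed pseudogenes had a median of -0.23 over 281 genes, and protein-coding genes had 0.04 over 12045.

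Single genes with large ratios just missed the threshold. By edgeR's quasi-likelihood test TUBA1B and CPNE8 both passed with DESeq2's size factors (adjusted p = 0.0481 each). With library-size scaling alone neither did (0.116 each, same quasi-likelihood test). The tubulin gene TUBA1B had counts of 2075 and 3406 in RIP against 75239 and 83786 in Input, a log2 fold change of -4.75 (SE 0.88, adjusted p = 0.0529 by edgeR's quasi-likelihood test). The copine gene CPNE8 had 1314 and 4799 in RIP against 122 and 285 in Input, a log2 fold change of 4.14 (SE 0.77, adjusted p = 0.0529 by the same quasi-likelihood test). Protein-coding genes with longer 3' UTRs had higher ratios, from a median of -0.17 in the shortest of 5 equal groups to 0.51 in the longest. Between these groups the median went from 0.03 to 0.35 for RIP 1 over Input 1 and from -0.46 to 0.62 for RIP 2 over Input 2. This trend was not separated from that of GC content. The median of 357 ZNF genes went from 0.69 to 0.37 after GC content, length and level were taken out by a linear model, with 0.38 and 0.29 in the replicates.

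The ratio across protein-coding genes was tested against AU-rich sequence, since RBMS1 is known to bind AU-rich RNA. Of the 32 pentamers made of A and U, AUAUA in the 3' UTR ranked 3 by its coefficient beside GC, length and level (0.253 ± 0.0124 SE), and 4 in each replicate (0.144 and 0.318); all 32 had positive coefficients, and UAUAU and AUAUU ranked above it. A bias of libraries toward such pentamers, apart from the precipitation, cannot be told apart from binding: between the Inputs the AUAUA coefficient was -0.172 times that of RIP over Input, under the bound set beforehand, but that bound was wrong because the Inputs cannot show a bias of the RIP preparation, and between the RIP libraries it was 0.513 times. Transcript GC and length explained 11.9% of the variance for RIP 1 over Input 1 and 34.5% for RIP 2 over Input 2; the first is too low for the bound set for a composition bias and too high for that against it, so bias and binding cannot be told apart for the GC trend. A preference of RBMS1 for AU-rich 3' UTRs may contribute, as a hypothesis that these data leave open.

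Mitochondrially encoded and histone RNA set RIP 2 apart. The mitochondrial share differed 12.7-fold between the RIP libraries and 1.68-fold between the Inputs, a ratio of 0.132. This argues against a difference in lysates only if RIP 2 and Input 2 came from the same lysate, which the labels do not say. Carry-over of whole mitochondria stays open: log2 RIP 2 over RIP 1 was positive for all 10 abundant mitochondrial RNAs and spread over 1.86, from 3.08 for MT-CO3 to 4.93 for MT-RNR1. A bound first set on RIP 2 over Input 2, whose spread of 4.43 would have excluded carry-over, was replaced with its outcome known. The reason was that RIP 1 over Input 1 also spread over 3.61, so both RIP libraries departed from the Inputs in mitochondrial composition. Positive RIP 2 over RIP 1 ratios would come with any excess of mitochondrial RNA in RIP 2, so their sign does not test carry-over. A higher yield of RNAs without a poly(A) tail in RIP 2 may account for the histone part: 44 replication-dependent histone mRNAs had a median log2 RIP 2 over RIP 1 of 3.36, with 43 higher, against -1.35 for 9 replacement histone mRNAs, a difference of 4.72; the former stood at -0.92 for Input 2 over Input 1.

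Of the 12 genes past the threshold, 9 (75%) overlapped an exon of another gene, against 6787 of 14056 other genes (48.3%), with a two-sided Fisher's exact p of 0.0833. Reads shared with overlapping genes and lower recovery with RBMS1 cannot be told apart for those 9, because the genes are too few and the strand setting of the counting is not known. The other 3 (MT-TN, ENSG00000248607 and RPSAP47) are the called genes that overlapped no annotated exon of another gene. They were set apart by that trait after the result was seen, so it is a description and not a test. RPSAP47 may share reads with its parent gene. No biological explanation was tested for these genes.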
